A study of Mus musculus with 6 samples.

How the data were processed

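MicroRNAs (miRNAs) were measured in MCT cells, a mouse renal tubular cell line of SJL background, on 6 one-colour arrays: 3 of control cells and 3 of cells given transforming growth factor beta (TGFβ) at 3 ng/ml for 72 hours. Per the labels' protocols, cells were grown with 10% fetal calf serum and moved to 0.5% serum before TGFβ was added, and 100 ng of total RNA was labelled with Cy3 for each array. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

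The deposited scanner files hold fluorescence intensity per spot, background-subtracted by Agilent Feature Extraction and not scaled between arrays, per the file headers. The file headers give version 10.7.3.1 of that software and the submitters' processing notes give 10.1.1, and the difference was left unresolved. The series value table held the same intensity values as the deposited scanner files, with a largest absolute difference of 0 on every array, so it adds no independent processing. The other deposited columns used were 0 or 1 flags for spots that were outliers, saturated or well above background, per the file headers. No spot was saturated. The array listed 611 mouse miRNA entries read by 1759 probes, with 1 to 4 probes per miRNA and 5 to 20 spots per probe, and 39 viral entries. Names are those of the array design. The headers name a genome build other than that of the gene table used here (GRCm38.p6), so no coordinates are given and that table served only to find which miRNA genes neighbour each other. Of the 84 tested miRNAs, 79 matched a gene symbol in it.

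Spots of a probe were averaged on the linear scale without outlier-marked spots, and the probes of a miRNA were then averaged. Each array was divided by its 75th percentile over the 105 probes well above background on all 6 arrays and multiplied by the geometric mean of those percentiles. A floor of 1 was then set and log2 taken. A probe counted as well above background where at least 0.5 of its spots did, and a miRNA where any of its probes did. A miRNA was tested if it was well above background on all 3 arrays of at least 1 group, which left 84. Of these, 14 were not well above background on every array, and their log2 differences depend on the floor or on signal near background. The number of arrays and the spread that control 1 brings both limit the precision. The median standard error (SE) of a log2 difference was 0.23 with all 6 arrays and 0.16 without control 1.

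Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). In 50 simulated data sets with the means and spread of the 84 miRNAs, limma recovered 16.6% of log2 changes of 0.5, 70.0% of changes of 1 and 92.0% of changes of 2, and called 0.921% of unchanged miRNAs. With the spread found without control 1 (85 miRNAs) the recovered shares were 31.7%, 81.1% and 92.6%, and 0.781% of unchanged miRNAs were called. The simulated noise was independent between miRNAs and of equal spread on every array. In the data control 1 departed from the other controls over many miRNAs, so these shares need not hold there. The 22 miRNA lists were tested with camera at a preset correlation of 0.01 against the other tested miRNAs where at least 2 members were tested, with camera at an estimated correlation, and with fry. In data simulated with independent noise for each miRNA, camera at an unadjusted p under 0.05 called the let-7 list, shifted by 0.5, in 100.0% of 50 data sets. It called 4.0% of unshifted lists. Members of real lists may vary together, so these shares need not hold for them. Array-level measures were compared by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

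The groups, the test, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule named the 5 miRNAs with the smallest p in each direction when none passed, the 2 members with the smallest p of each list, the 5 with the highest mean signal, miRNAs well above background in 1 group only, and miR-21, miR-192, miR-200a, miR-200b, miR-200c, miR-29b, miR-34a and miR-34c. Outside this rule, miR-34b-5p, miR-449a, miR-20a, miR-30c, miR-130a, let-7g, miR-1224 and those that appear only in the closing section were chosen after their values were seen. The alternatives changed the scaling, the background correction, the summary over probes, the filter on dim miRNAs, the floor, the variance model, the array weights, the threshold, blocking and the arrays used. Normexp was run with an added offset of 50 intensity units, which shrinks log2 differences of dim miRNAs by construction. The planned normexp correction on mean spot signal was not run because that column is not in the files used here, and the median spot signal took its place. That alternative, the slide column as a block, the comparison within slide row 1, scaling by the labelling spike-in, and leaving out control 1 together with TGFβ 1 or with TGFβ 2 were chosen after seeing the data.

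All 6 arrays lay on 1 slide and were scanned once. Column 1 of the slide held control 1 and TGFβ 2, and column 2 held control 2 and TGFβ 3. Control 3 and TGFβ 1 were alone in their columns. Row 1 held the 3 controls and TGFβ 1, and row 2 held TGFβ 2 and TGFβ 3. Arrays with the same replicate number deviated together from their group means, with correlations across miRNAs of 0.38, 0.37 and 0.52 for numbers 1, 2 and 3, so the numbers were taken to pair the arrays. That pairing comes from the data alone and was not tested, and control 2 correlated slightly more with TGFβ 3 (0.38) than with TGFβ 2. Deviations from the mean of 3 arrays sum to 0, so these correlations are not independent of each other. Controls 2 and 3 were closest of all pairs but were not the same measurement: 30.5% of the 105 probes differed beyond spot error at a 5% level.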

Results

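The series asked how TGFβ, a cytokine that drives fibrosis and loss of epithelial character in tubular cells, alters miRNAs in MCT cells. Control cells (3 arrays) were compared with cells given TGFβ at 3 ng/ml for 72 hours (3 arrays). Between 74 and 103 of 611 mouse miRNAs were well above background per array, and 504 were not on any array. The numbers were 86, 75 and 74 in controls 1 to 3, and 103, 89 and 86 in TGFβ 1 to 3. The 75th percentile used for scaling lay between 249.5 and 402.4 intensity units. Values below are log2 scaled signals.

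MCT cells gave high signal for miR-21, which is raised in injured and fibrotic kidney, with 11.38 ± 0.34 in control and 11.78 ± 0.34 in TGFβ-treated cells (SD, n = 3). The signals of let-7b (10.61 ± 0.10 and 10.48 ± 0.19), let-7c (10.11 ± 0.23 and 9.98 ± 0.20) and miR-15b (10.06 ± 0.21 and 9.77 ± 0.24) were also high. Members of the miR-200 family, which hold cells in an epithelial state by repressing Zeb1 and Zeb2, were not well above background on any array (0 of 5 members). The same held for miR-192, a kidney-enriched miRNA, for 0 of 5 members of the mesenchymal list of miR-199 and miR-214, and for 0 of 3 of the smooth muscle list of miR-143 and miR-145. None of 6 blood cell and 2 endothelial markers was well above background either. Of 10 muscle, neuron, liver and islet markers only miR-206 was, on control 1 and the 3 TGFβ arrays. No fold is given for miRNAs below background in both groups.

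With all 6 arrays, the miRNAs with the lowest p among those higher in TGFβ-treated cells were miR-125b-5p, miR-714, miR-689, miR-181b and miR-25, and among those lower miR-98, miR-324-5p, miR-130b, miR-10b and miR-10a. None of the 84 tested miRNAs passed the threshold in limma, where the smallest adjusted p was 0.391. At an unadjusted p under 0.05 there were 8, of which 5 were higher and 3 lower. miR-125b-5p read 6.73 ± 0.56 in control and 7.73 ± 0.27 in TGFβ-treated cells (SD, n = 3), a log2 difference of 1.00 (SE 0.32, limma adjusted p = 0.391). miR-25, from the miR-106b cluster, differed by 0.34 (SE 0.13) with little spread in either group, 8.52 ± 0.07 against 8.86 ± 0.05 (SD, n = 3), and its limma adjusted p was also 0.391. miR-98, a let-7 family member, differed by -0.53 (SE 0.18), miR-324-5p by -0.55 (SE 0.22), miR-130b by -0.35 (SE 0.14), miR-10b by -0.52 (SE 0.22) and miR-10a by -0.35 (SE 0.16). With normexp these differences were -0.30, -0.34, -0.27, -0.31 and -0.28 in the same order. The groups did not overlap for 12 miRNAs, 7 higher and 5 lower, which is 14.3% of those tested. Chance gives 10% for 3 against 3 only where miRNAs are chosen without regard to group. The filter also admitted miRNAs well above background throughout 1 group only. Among the 12, miR-714, miR-689 and miR-181b entered that way, with 1 control array each, so the 10% is no exact reference.

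Several of the miRNAs with large differences were dim in control cells. miR-714 was at the floor on controls 2 and 3 and well above background on 1 control, and its log2 difference of 4.21 (SE 1.36) was 2.63 with a floor of 5, 2.72 without TGFβ 1 and 0.58 with normexp. With the replicate number as a block, a pairing the labels do not state, it alone passed (limma adjusted p = 0.0029), so the count went from 0 to 1. miR-689 had floor values too, with 4.33 ± 0.34 in TGFβ-treated cells (SD, n = 3), 3.84 on control 1 and the floor on controls 2 and 3, and its difference of 3.05 (SE 1.06) was 1.4998 with a floor of 5 and 0.0334 with normexp. miR-494, of the imprinted Dlk1-Dio3 locus, read 11.62 on TGFβ 1 and between 2.64 and 5.69 on the other arrays. Without TGFβ 1 its difference moved from 3.82 (SE 1.92) to 1.60, and with normexp to 1.76. miR-1906 was well above background on the 3 TGFβ arrays and on no control array, but the bound set by the dimmest probes above background gave no fold. miR-181b differed by 0.83 (SE 0.30) and was well above background on 1 control array, and with normexp its difference was 0.0102. The normexp offset of 50 pulls the differences of dim miRNAs towards 0 by construction, so these small values do not show that a change is absent.

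By the median absolute log2 difference over the 84 miRNAs, control 1 lay closer to the TGFβ arrays than to the other controls. It was 0.16 between control 1 and TGFβ 3, 0.21 between control 1 and TGFβ 2, 0.26 between control 1 and TGFβ 1, and 0.48 and 0.52 between control 1 and controls 2 and 3. Controls 2 and 3 differed by 0.06. By the Pearson correlation this held for TGFβ 2 (0.981) and TGFβ 3 (0.969) but not for TGFβ 1 (0.808), against 0.907 and 0.899 for controls 2 and 3.

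**Figure D1:**
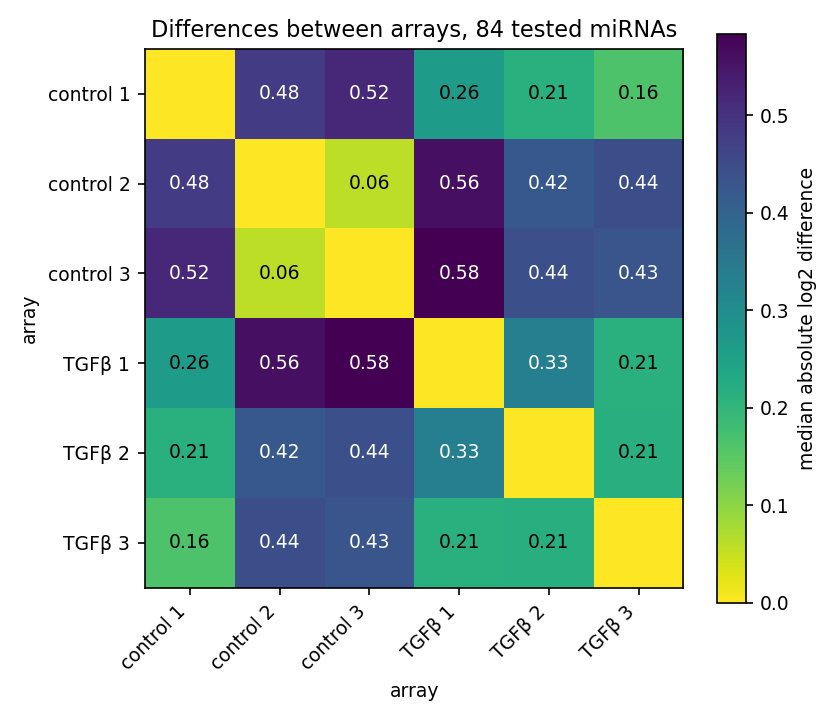
Median absolute log2 difference over 84 tested miRNAs between each pair of the 6 arrays, with arrays on both axes and the value in each cell. Control 1 differs from the TGFβ arrays by 0.16 to 0.26 and from controls 2 and 3 by 0.48 and 0.52.

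Without control 1, 31 of 85 miRNAs passed in limma, 11 higher and 20 lower in TGFβ-treated cells, and leaving out any other single array gave 0. Control 1 is the control that lay with the TGFβ arrays, so leaving it out tends to widen the differences and lower the spread. The adjusted p-values of this fit do not allow for that choice of array. The miR-34 family, known as transcriptional targets of p53, was higher: miR-34c by 1.37 (SE 0.18, limma adjusted p = 0.0157), miR-34a by 1.31 (SE 0.15, limma adjusted p = 0.014) and miR-34b-5p by 1.02 (SE 0.17). These are 2.58, 2.49 and 2.03 times the level on controls 2 and 3. miR-125b-5p (1.32, SE 0.18), miR-20a (0.71, SE 0.14) and miR-29a (0.63, SE 0.14) were higher too. miR-181b, miR-206, miR-20b, miR-449a and miR-689 also passed, but they were not well above background on controls 2 and 3, and their bounds gave no fold. On the lower side, miR-30c (-1.48, SE 0.31) and miR-30a (-0.998, SE 0.22) belong to the miR-30 family, which is abundant in kidney epithelium, and the opposite arm miR-30a* (-1.16, SE 0.17) was lower too. miR-30c was well above background on controls 2 and 3 but on only 2 of 3 TGFβ arrays, so the size of its difference rests partly on signal near background. Others lower were miR-27b (-1.02, SE 0.18), miR-23b (-0.75, SE 0.13), miR-221 (-0.81, SE 0.14), miR-130a (-0.77, SE 0.12), let-7d (-0.76, SE 0.20) and let-7g (-0.61, SE 0.12). miR-21 did not pass in that fit (0.58, SE 0.23, limma adjusted p = 0.112); with all 6 arrays it differed by 0.40 (SE 0.26), and quantile normalization turned this to -0.60. Over all alternatives the limma adjusted p lay between 0.00472 and 0.976 for miR-34a, 0.00594 and 0.976 for miR-34c, 0.0146 and 0.976 for miR-21, and 0.00291 and 0.976 for miR-714. With all 6 arrays the log2 difference was 0.87 (SE 0.40) for miR-34a, 0.93 (SE 0.40) for miR-34c (0.33 with normexp), -0.68 (SE 0.33) for miR-30a and -0.51 (SE 0.27) for let-7d, and none passed.

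**Figure D2:**
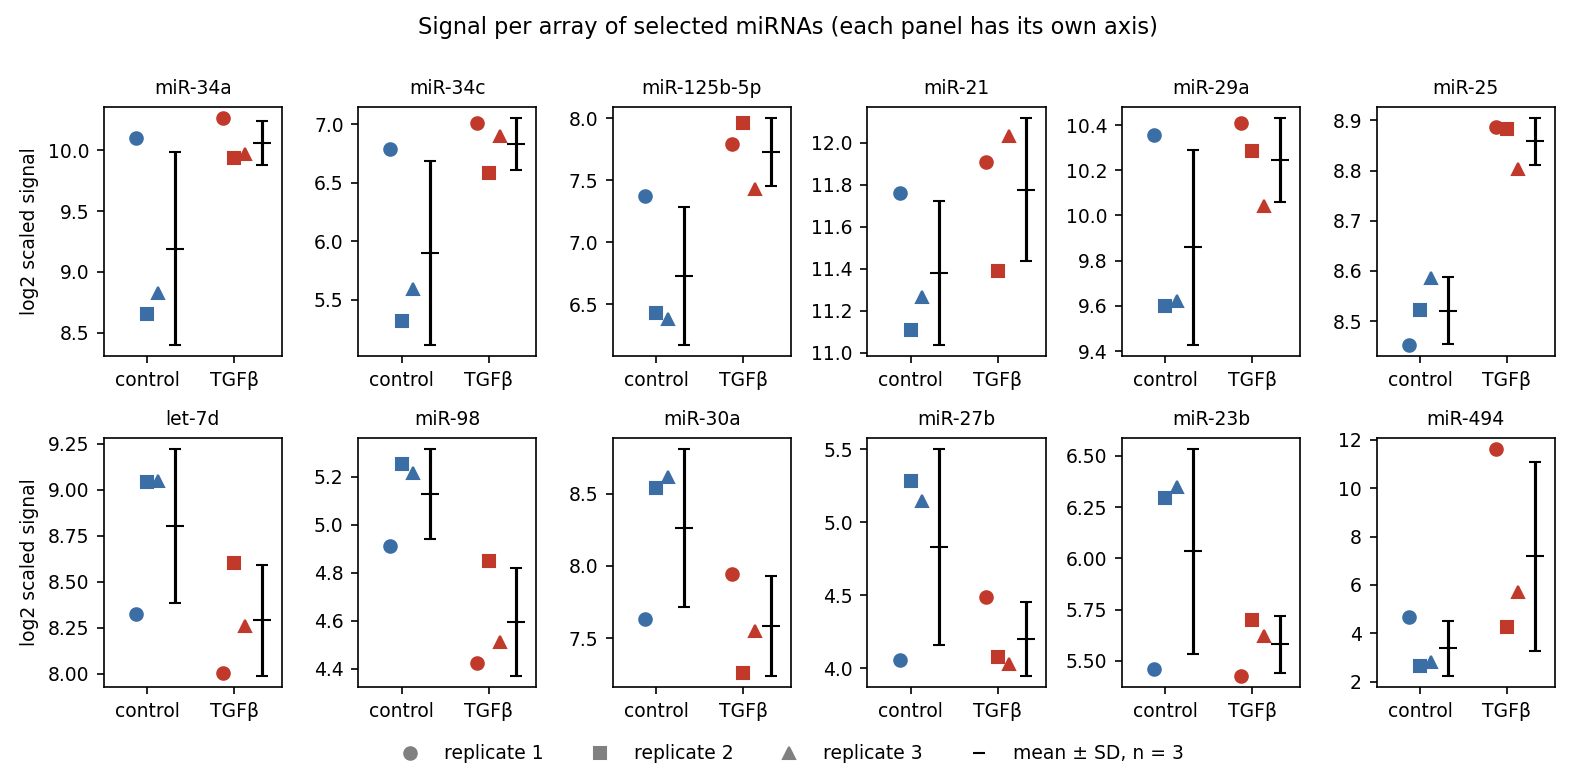
Log2 scaled signal of 12 miRNAs on each of the 3 control (blue) and 3 TGFβ (red) arrays, with replicates as symbols and bars for mean ± SD (n = 3). For miR-34c, control 1 (6.79) sits with the TGFβ arrays (6.58 to 7.01), apart from controls 2 and 3 (5.32 and 5.59).

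The slide columns that held both groups gave different answers. In column 1, TGFβ 2 minus control 1 was -0.16 for miR-34a, -0.21 for miR-34c, -0.38 for miR-21, -0.37 for miR-30a and 0.28 for let-7d. In column 2, TGFβ 3 minus control 2 was 1.32, 1.59, 0.93, -0.99 and -0.78 for the same miRNAs. For miR-125b-5p both columns gave a positive value, 0.59 and 1.00. With the column as a block 0 of 84 miRNAs passed in limma. With the slide row as a block the TGFβ side is the single array TGFβ 1, and the 3 that passed (miR-494, miR-1224 and miR-714) are among the 15 that read at least 2 log2 units higher on that array than on any other.

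Of the 22 miRNA lists, 11 had 2 or more tested members, and camera called 4 with all 6 arrays. The family of miR-34 and miR-449 was higher on average by 0.66 ± 0.30 (SD over 4 members, 4 of 4 higher, adjusted p = 0.0419), and the miR-17/92 and paralogous clusters, known to promote proliferation, by 0.27 ± 0.21 (8 members, 6 of 8 higher, adjusted p = 0.0419). Without TGFβ 1 the miR-17/92 mean was 0.16 (adjusted p = 0.201) and that of miR-34 and miR-449 was 0.57 (adjusted p = 0.105), and with normexp they were 0.08 (adjusted p = 0.0514) and 0.26 (adjusted p = 0.0789). Neither call held with an estimated correlation (adjusted p = 0.506 for both). The let-7 family was lower by -0.28 ± 0.17 (9 of 9 members lower, adjusted p = 0.0419), a direction that turned to 0.06 without scaling between arrays, and with -0.23 without TGFβ 1 it did not pass (adjusted p = 0.201). A list of GC-rich or fragment-derived array entries, fixed as a technical control, was higher by 2.11 ± 2.05 (4 of 5 members, adjusted p = 0.045). Its mean was 1.25 without TGFβ 1 (adjusted p = 0.105), 1.49 with a floor of 5 (adjusted p = 0.0571) and 0.68 with normexp (adjusted p = 0.0755). The let-7 and technical calls did not hold with an estimated correlation either (adjusted p = 0.506 for both), and fry gave adjusted p of 0.356 or more for every list. No member passed in limma, over all miRNAs or adjusted over the list alone. With the replicate block, 2 lists passed, the miR-34 and miR-449 family (adjusted p = 0.0389) and the technical list (adjusted p = 0.0217), while the let-7 (adjusted p = 0.0502) and miR-17/92 (adjusted p = 0.151) lists did not. With that block and an estimated correlation 0 lists passed (smallest adjusted p = 0.546). Within column 1 the means of the lists of miR-34 and miR-449, miR-17/92, let-7 and technical entries were -0.30, -0.19, 0.22 and -0.13, and within column 2 they were 1.11, 0.36, -0.55 and 2.10.

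Without control 1, camera called the miR-34 and miR-449 family (mean 1.06, adjusted p = 0.00589, with 4 of 4 members passing) and the miR-17/92 list (mean 0.41, adjusted p = 0.022, with 2 of 8 passing). With an estimated correlation neither held (adjusted p = 0.454), while fry in one direction called both (adjusted p = 0.0152 and 0.0423) among 7 of 11 lists. The technical list was also among these 7 (fry adjusted p = 0.041), so the fry calls do not set the miRNA families apart from it. Over all alternatives the camera adjusted p lay between 0.00589 and 0.817 for the miR-34 and miR-449 family, and 0.00633 and 0.571 for the miR-17/92 list. Without control 1, 9 of 9 let-7 members, 5 of 5 members of the miR-23/27/24 clusters and 2 of 3 tested miR-30 members were lower. Of these, 3, 3 and 2 passed in limma, with the same counts adjusted over the list alone. Camera did not call these lists (adjusted p = 0.0634, 0.0842 and 0.313), and miR-30d was higher by 0.17 without passing. Fry in one direction called the miR-23/27/24 clusters (adjusted p = 0.00224) but not the let-7 (adjusted p = 0.0684) or miR-30 (adjusted p = 0.164) lists. With each of controls 2 and 3 and TGFβ 1 left out in turn, camera called 0 lists, and without TGFβ 3 it called 1. Without TGFβ 2 it called 3: let-7 (mean -0.40, adjusted p = 0.00305), miR-17/92 (mean 0.35, adjusted p = 0.0246) and technical entries (mean 2.60, adjusted p = 0.0303). With an estimated correlation camera called 0 lists in either of these fits (smallest adjusted p = 0.578 without TGFβ 3 and 0.485 without TGFβ 2).

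The other lists did not pass with all 6 arrays. The miR-29 family, which targets collagen mRNAs, was higher in 3 of 3 members, with a mean of 0.25 (camera adjusted p = 0.282), and miR-29b differed by 0.23 (SE 0.37), but the list mean was 0.0531 without TGFβ 1 and -0.0313 with the slide column as a block. The miR-23/27/24 clusters were lower in 5 of 5 members (mean -0.30, adjusted p = 0.219), the miR-15/16 family in 3 of 3 tested (mean -0.26, adjusted p = 0.227) and the kidney tubule list in 4 of 4 tested (mean -0.29, adjusted p = 0.118). The kidney tubule list had 10 entries on the array. Its tested members were of the miR-10 and miR-196 families only, and miR-192 was among those not tested. Without control 1 the means of these 3 lists were -0.54, -0.40 and -0.39. All 3 lists turned positive without scaling between arrays, which moved the median over all tested miRNAs from -0.09 to 0.26. miRNAs reported to rise with TGFβ or in renal fibrosis went both ways, 3 of 6 tested members higher and 3 lower, with a mean of 0.15 and a median of -0.00036 (adjusted p = 0.47). That mean was 0.08 without TGFβ 1 and -0.00064 with normexp. The miR-30 family had 1 member higher and 1 lower (mean -0.20, adjusted p = 0.789). Its mean was -0.37 without TGFβ 1 and -0.77 without control 1 (3 tested), but 0.14 without scaling and 0.18 with total gene signal. The passenger strands had 2 of 2 lower (mean -0.45, adjusted p = 0.307). Lists with a single tested member had miR-322 (-0.23), miR-221 (-0.33), miR-206 (0.60), miR-155 (0.05) and miR-494 (3.82), of which miR-322 and miR-221 turned positive without scaling, miR-206 turned negative with normexp, and miR-155 turned negative under several alternatives. The Sfmbt2 cluster had 0 tested members.

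Array-level measures were compared between the groups. The labelling spike-in signal (log10) was 2.01 ± 0.16 in control and 2.14 ± 0.0056 in TGFβ arrays (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.24), with 1.82 on control 1. The median local background was 55.7 ± 0.58 and 53.7 ± 0.58 intensity units (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.24). The number of miRNAs well above background was 78.3 ± 6.66 and 92.7 ± 9.07 (SD, n = 3, exact permutation p = 0.2), and the share of signal in the 10 brightest miRNAs 52.9 ± 2.27% and 62.6 ± 12.3% (SD, n = 3, exact permutation p = 0.2). The 75th percentile had an exact permutation p of 0.2 and the median coefficient of variation (CV) of spots one of 1. No exact permutation test of 3 against 3 arrays can go below 0.1. TGFβ 1 held 76.9% of its signal in its 10 brightest miRNAs, and between 51.5% and 56.0% was found on the other arrays. Of the 19 technical list entries, 6, 3 and 3 were well above background on controls 1 to 3, and 11, 6 and 5 on TGFβ 1 to 3.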

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

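The tests of array brightness and of the technical list below were chosen after the result was seen. An entry for a viral miRNA, mcmv-miR-M23-1-5p of murine cytomegalovirus, which none of the comparisons used, had a mean processed signal of 83.2 on TGFβ 1 and at most 4.24 on the other 5 arrays. It was the only 1 of 39 viral entries well above background on any array.

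The same array carried 15 mouse miRNAs at least 2 log2 units above each other array, while no other array had any. They included miR-1224 (14.48, and between 6.45 and 8.64 elsewhere), miR-494 and miR-714. Of 255 spots on their probes well above background on TGFβ 1, 98.4% exceeded every spot of the same probe on the other arrays. On these probes the signal did not rest on a few spots. Probes with only a few bright spots were left out of this count, so it cannot exclude defective spots there. A brighter array does not account for the 15 miRNAs. Before scaling, the other 81 tested miRNAs lay above the mean of the other arrays by a median of only 0.16 log2 units (quartiles 0.03 and 0.63). The unscaled 75th percentile of TGFβ 1 (365.3) was below that of TGFβ 2 (402.4). The share of technical list entries was 40.0% among the 15 and 2.18% among all other mouse entries (two-sided Fisher's exact test, p = 1.63e-06). Standing out required signal well above background on TGFβ 1, and 11 of the 103 miRNAs with such signal were on that list. The 2.18% and the p therefore overstate the contrast. Nonspecific signal of GC-rich or fragment-derived entries is a candidate explanation for part of the 15, and 9 of the 15 are not on that list. A response to TGFβ was not tested for this array alone, as TGFβ 2 and 3 had the same treatment.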

How the results depend on the processing

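Array signal over background limits the results: 504 mouse miRNAs were not well above background on any array, and 14 tested ones were not on all. The alternatives named in the methods as chosen after seeing the data are normexp, the column block, row 1 alone, spike-in scaling and the removal of control 1 together with TGFβ 1 or with TGFβ 2, and the planned normexp on mean signal was not run. The count of changed miRNAs was 0 in all alternatives except the comparisons by slide row and these: 45 (18 higher, 27 lower) with array weights, whose estimation stopped before convergence and gave control 1 a weight of 0.144, 1 with the replicate block, 31 without control 1, 35 (15 higher, 20 lower) without control 1 and TGFβ 1, and 38 (13 higher, 25 lower) without control 1 and TGFβ 2. The slide row as a block gave 3 and row 1 alone 6, but there the TGFβ side is the single array TGFβ 1 and every call is among the 15 miRNAs that stood out on it. Of the 31, 29 were among the 35, all 29 in the same direction. Leaving out each array in turn gave 0 to 31 miRNAs and 0 to 3 lists. The list count of 4 became 0 with scaling by all probes, no scaling, normexp, total gene signal, estimated correlation and fry in either form, 1 with the column block and spike-in scaling, and 2 with the mean of log2 over probes, detection on all arrays, the replicate block and the removal of control 1 and TGFβ 1. It was 3 with quantile normalization, a floor of 5, array weights and the row block, and 5 with no filter. With an estimated correlation it was 0 under every alternative. The replicate block changed no call besides miR-714 and the let-7 and miR-17/92 lists. Quantile normalization turned miR-21 to -0.60 and miR-155 to -0.0023. No scaling turned miR-322 (0.12), miR-15b (0.0477), miR-221 (0.0108), miR-674* (0.0539), let-7b (0.22), let-7c (0.22) and the lists miR-30 (0.14), let-7 (0.0603), miR-23/27/24 (0.0465), miR-15/16 (0.0835) and kidney tubule (0.0505), by its construction, as the mean 75th percentile was 369.2 on TGFβ and 293.9 on control arrays. Normexp turned miR-30d (-0.13), miR-20b (-0.11), miR-206 (-0.10), miR-155 (-0.11), miR-1906 (-0.0745) and the list of miRNAs reported up with TGFβ (-0.00064). It also moved 14 of the 33 tested named miRNAs towards 0 by over 1.5 times without turning them, among them miR-125b-5p (1.00 to 0.60). For dim miRNAs its offset of 50 does this by construction. Total gene signal turned let-7b (0.016), let-7c (0.017) and the miR-30 list (0.18). The row block turned miR-155 (-0.0272) and the miR-30 list (0.13), row 1 alone turned miR-155 (-0.0272) and the passenger strands (1.38, 4 tested), and spike-in scaling turned miR-155 (-0.0473). The column block turned miR-29b (-0.17) and the miR-29 list (-0.0313). Leaving out single arrays gave -0.0802 to 0.54 for miR-29b, -0.0225 to 0.12 for miR-155, and -2.41 to 2.74 percentage points for the spot CV. None of the reversed miRNAs or lists passed its test with the sign turned, and the cause was not tested except where stated.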

Other observations

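The tests of the shared slide column, of a wrong label, of slide column 1 and of neighbouring genes were chosen after the result was seen. miRNAs whose genes lie close together gave similar log2 differences. Among 27 pairs of tested miRNAs with genes within 10 kb of each other in the GRCm38.p6 table, formed by 31 miRNAs, the mean absolute difference between partners was 0.25 with all 6 arrays, and 0.43 after shuffling the values over these miRNAs (one-sided permutation p = 0.00046, 100000 resamples). Partners had the same sign in 19 of 27 pairs. For example, miR-25 and miR-93 differed between the groups by 0.34 and 0.45, and miR-23b and miR-27b by -0.45 and -0.63, while miR-182, miR-183 and miR-96 of another cluster had 0.29, -0.07 and -0.35. None of these passed in limma with all 6 arrays. The 13 pairs of different families, formed by 14 miRNAs, gave a one-sided permutation p = 0.01, with 8 of 13 of the same sign. Pairs from the cluster of miR-23b and miR-27b and from its paralogous cluster all shared a sign, while most of the others did not. These related clusters supply most of the same-sign pairs, and members of one family stayed among the shuffled miRNAs. The test therefore cannot exclude signal shared between probes of related sequence. Shared transcripts are a candidate explanation. miRNAs of one cluster are not independent, and the test says nothing about whether TGFβ moved them.

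Control 1 resembled the TGFβ arrays, and this array decides the count of changed miRNAs. Over the 31 miRNAs that passed without it, its median position was 1.09 (quartiles 0.88 and 1.22) on a scale from 0 at controls 2 and 3 to 1 at the TGFβ mean. RNA of the TGFβ condition under a wrong label would lie near 1. None of these miRNAs passed with control 1 included, so its position largely restates the resemblance. Other causes of the resemblance would also put it near 1. Control 1 shared its slide column with TGFβ 2. Of 38 miRNAs that passed in limma without both arrays of that column, control 1 was nearer to TGFβ 1 and 3 than to controls 2 and 3 for 89.5%. Its median position was 1.01 (quartiles 0.80 and 1.20). This argues against a column effect unrelated to the differences of TGFβ 1 and 3 from controls 2 and 3. The 38 miRNAs were read on the same arrays and are not independent. A column effect along those same differences cannot be excluded with 1 such control array. A smooth trend of control 1 on mean signal did not account for all of the resemblance either. After a loess trend was removed, control 1 stayed nearer to the TGFβ mean for 80.0% of 30, with a median position of 0.84. That trend was removed from control 1 alone. Controls 2 and 3 were the dimmest arrays (75th percentile 268.6 and 249.5, against 339.9 to 402.4 elsewhere). Whether array brightness lies behind their differences from the TGFβ arrays was not tested. No TGFβ array resembled controls 2 and 3 in turn, with median absolute differences of 0.42 to 0.58. This argues against an exchange of labels between control 1 and a TGFβ array. Control 1 also had the lowest labelling spike-in signal (log10 1.82, and 2.09 to 2.14 elsewhere), and a link to the pattern was not tested. A wrong label of another kind may explain the pattern, and a difference between cultures of control cells stays open and was not tested.

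On both arrays of slide column 1, miR-202-3p (7.88 on control 1 and 7.63 on TGFβ 2) and miR-1904 (7.55 and 7.33) were higher than on the other 4 arrays (5.24 to 5.77 and 4.70 to 5.90). For both miRNAs all 3 TGFβ arrays lay below control 1, so the arrays do not part by treatment. The 2 miRNAs were chosen for this pattern, so this is no separate test of treatment. Deviations of 1028 spots from their probe mean correlated at 0.81 between these arrays and at 0.31 or less between any other pair, and the median CV of spots was 15.6% and 14.8% against 6.55% to 7.95% elsewhere. A property of the slide column, such as printing or hybridization, is a candidate explanation.

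Of the 10 splits of the 6 arrays into 3 and 3, all gave 0 changed miRNAs, the real one and the highest other alike. For lists the real split gave 4, the highest other 5, and 2 of 10 splits gave at least 4. The split with 5 set control 1, TGFβ 1 and TGFβ 3 against the rest. Among the 4 splits that part all 3 replicate pairs, the other splits gave 0 or 1 list. With 10 splits, or with these 4, no share under 0.05 can be reached.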
